A study of Mus musculus with 4 samples.

How the data were processed

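Single-cell ATAC sequencing, which uses the Tn5 transposase to cut and tag accessible chromatin and a droplet barcode to assign each fragment to a cell, was applied to flash-frozen entorhinal cortex of wild-type C57Bl6 mice at postnatal day 56. Per the labels, 2 samples came from the medial entorhinal cortex (MEC) and 2 from the lateral entorhinal cortex (LEC), dissected from both hemispheres, with 2 mice in all. The labels number the samples of each region 1 and 2 but do not say whether a number marks a mouse. Nothing states that the 2 samples of a region came from separate animals, so the spread between them may be technical.

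Each sample had 1 deposited table with 1 row per barcode. Per the file headers, the authors' values are counts of read pairs per barcode, split into duplicate, chimeric, unmapped, low mapping quality, mitochondrial and usable pairs, and counts of usable unique fragments that overlap transcription start sites (TSSs), promoters, enhancers, DNase-sensitive regions, blacklisted regions and peaks. A further column, with unit other, is the authors' 0 or 1 call of a barcode as a cell. The submitters' processing notes name the builds mm10 and GRCm38, and the labels refer to the 10X protocol. The aligner, cell caller, peak caller and their versions are not given in the sources used here, nor is it stated whether peaks were called per sample or on pooled samples or which annotation defines the region classes. The tables hold no gene, peak or cluster, so no gene or cell type is reported. The 6 classes of read pairs summed to the total in 100% of rows. The row of reads without a valid barcode held between 1.93% and 1.98% of the read pairs of a library. It is included in the total read pairs per library and was left out of all other values.

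Called barcodes are referred to as nuclei. No doublet caller was run, since the tables hold no counts per locus, and the sources used here do not say whether the authors removed doublets. Called barcodes reached 202977 fragments. Shares were computed per library as summed fragments of a class over summed usable fragments of the called nuclei, the mitochondrial share over all read pairs, and the duplicate share over duplicate plus usable pairs. A fragment can count in several classes, so the shares do not add up to a whole. Nuclei were not treated as replicates. Each value was compared between regions with a two-sided exact permutation test of the difference of means over the 4 libraries (6 assignments). With 2 libraries against 2, the smallest p this test can give is 0.333, so no comparison could pass 0.05, and the values with their SD are the result. Counting intervals (Wilson, 95%) of the shares were at most 0.0145 percentage points to either side. They cover counting error only, since fragments of 1 nucleus are not independent. Total depth ranged from 114232167 to 146431311 read pairs per library.

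Distributions of nuclei were compared with the Kolmogorov-Smirnov distance for each of the 3 ways to divide the libraries into pairs. Barcodes called in both of 2 libraries were counted against a hypergeometric expectation over barcodes listed in both tables, with Benjamini-Hochberg adjustment over the 6 pairs. The tests, the samples in them, the rule that every region class is named and most alternatives were fixed before the data were examined. The alternatives were other definitions of a nucleus (at least 1000 or 5000 usable fragments, or called nuclei with 3000 to 50000 fragments, at least 15% of them in peaks and under 5% in blacklisted regions), medians and means per nucleus, weighting to 1 depth distribution in bins of 0.25 on the log10 scale, other denominators, subtraction of the share in uncalled barcodes, an estimate of library complexity, a replicate block and leaving out each library.

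After the data had been seen, Gaussian mixtures with 1, 2 or 3 components were fitted to the log2 enhancer to promoter ratio of nuclei with at least 5000 usable fragments, and compared by the Bayesian information criterion (BIC). On simulated data for MEC replicate 1 (1019 nuclei, 40% in the lower component), the 2-component fit returned 41.5% and was preferred by 163 BIC units, while a single simulated component gave -23.3. The other 3 libraries returned 42.8%, 39.6% and 39.6%. The same comparison was made after a cubic trend with log10 fragments had been removed from the ratio, and in strata of 10000 fragments from 20000 to 70000. The TSS difference at 1 common mix of low-ratio and high-ratio nuclei was computed with the boundary fitted per library and with boundaries of 1.5, 1.6 and 1.7 for all libraries, and each of these is reported. Depth weighting was tested on simulated libraries that differed by depth alone, where a difference of 0.459 percentage points became 0.0299. The simulated share depended on usable fragments alone, so weighting on them was bound to remove the difference. Unequal sequencing of nuclei of equal complexity was not simulated. Reads at barcodes called in another library were set against control barcodes with at most 10 read pairs in that library that were called in none. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0, with figures drawn in matplotlib 3.10.9.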

Results

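The study asked which excitatory cell types the medial and lateral entorhinal cortex have in common. These adjoining cortical areas are the main cortical gateway to the hippocampus, with the MEC known for spatial coding and the LEC for coding of objects. Chromatin accessibility was profiled in 4 libraries, 2 from each region, and the per-barcode counts analysed here describe how the accessible fragments of their nuclei were distributed over promoters, enhancers and other annotated classes. The libraries held 146431311 read pairs in MEC replicate 1, 143422912 in MEC replicate 2, 118619185 in LEC replicate 1 and 114232167 in LEC replicate 2. In all, 4086 barcodes had been called as nuclei by the authors. The 2 MEC libraries shared 2 called barcodes and the 2 LEC libraries shared 1, so the replicates were separate libraries.

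The difference in numbers of nuclei depended on how a nucleus was defined. By the authors' calls MEC libraries held 1005 ± 60.8 nuclei and LEC libraries 1038 ± 60.8 (SD, n = 2 for this and all following group values). The difference of 33 nuclei was smaller than the spread between libraries of 1 region (exact permutation p = 0.667), and the sign of the difference turned when MEC replicate 2 or LEC replicate 1 was left out (10 nuclei more in MEC either way). Within replicate numbers MEC held 33 fewer in both pairs, and replicate 1 held 86 more than replicate 2 in both regions. No label says whether the numbers pair the libraries. Under 2 other definitions both MEC libraries lay below both LEC libraries (exact permutation p = 0.333, the smallest possible), with 1291 ± 60.8 barcodes of at least 1000 fragments against 1431.5 ± 112, and 416 ± 45.3 against 568 ± 38.2 under a stricter filter. At 5000 fragments they were 1122 ± 65.1 and 1213 ± 94.8 (exact permutation p = 0.667). The stricter filter leaves out nuclei above 50000 fragments, a limit below the median of MEC nuclei and above that of LEC nuclei. It thus removes more nuclei from the more deeply sequenced MEC libraries, and its difference is no sign of fewer nuclei there. MEC nuclei yielded more unique fragments, with a median of 60063 ± 2278 against 43913 ± 430 in LEC, a 1.37-fold difference. Every MEC library lay above both LEC libraries. MEC nuclei had also been sequenced more deeply, with 88653 and 95278 read pairs per nucleus against 59427 and 63496 in LEC, and 28.4% ± 0.298 of their pairs were duplicates against 20.6% ± 0.587. With the number of distinct fragments estimated from the duplicates, the regions had nearly equal complexity, at 116861 ± 4336 fragments per nucleus in MEC and 116849 ± 1357 in LEC. The 1.37-fold difference in fragments per nucleus was thus not seen in the estimated complexity.

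A larger part of the usable fragments of MEC nuclei lay at TSSs, promoters, enhancers and DNase-sensitive regions, although over all read pairs this order held for promoters only. At TSSs, where transcription of genes begins, the share was 18.9% ± 0.0655 in MEC and 17.2% ± 0.0996 in LEC. At promoters it was 13.2% ± 0.0766 against 11.4% ± 0.0901, a 1.16-fold difference and the largest relative one among TSSs, promoters, enhancers and DNase-sensitive regions. Enhancers, distal elements that regulate genes from afar, took 23.3% ± 0.0945 of fragments in MEC and 22.3% ± 0.0105 in LEC. DNase-sensitive regions, stretches of chromatin open to digestion by DNase, took 36.3% ± 0.121 in MEC and 33.7% ± 0.0369 in LEC. Blacklisted regions, which collect artefactual signal, held 0.305% ± 0.000147 of MEC fragments and 0.253% ± 0.00333 of LEC fragments. For each of these classes both MEC libraries lay above both LEC libraries, and the difference exceeded the replicate SD. The exact permutation test gave p = 0.333 for each, the smallest it can give here. Of the 12 quantities compared in this way, 11 separated the regions, where chance separates 33.3% of such quantities if the 4 libraries are exchangeable. Separation is more likely than that if the 2 libraries of a region are technical replicates, which the labels leave open. These quantities are also not independent of each other. The adjusted p was 0.364 for these 11 (exact permutation test, Benjamini-Hochberg over the 12).

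**Figure D1:**
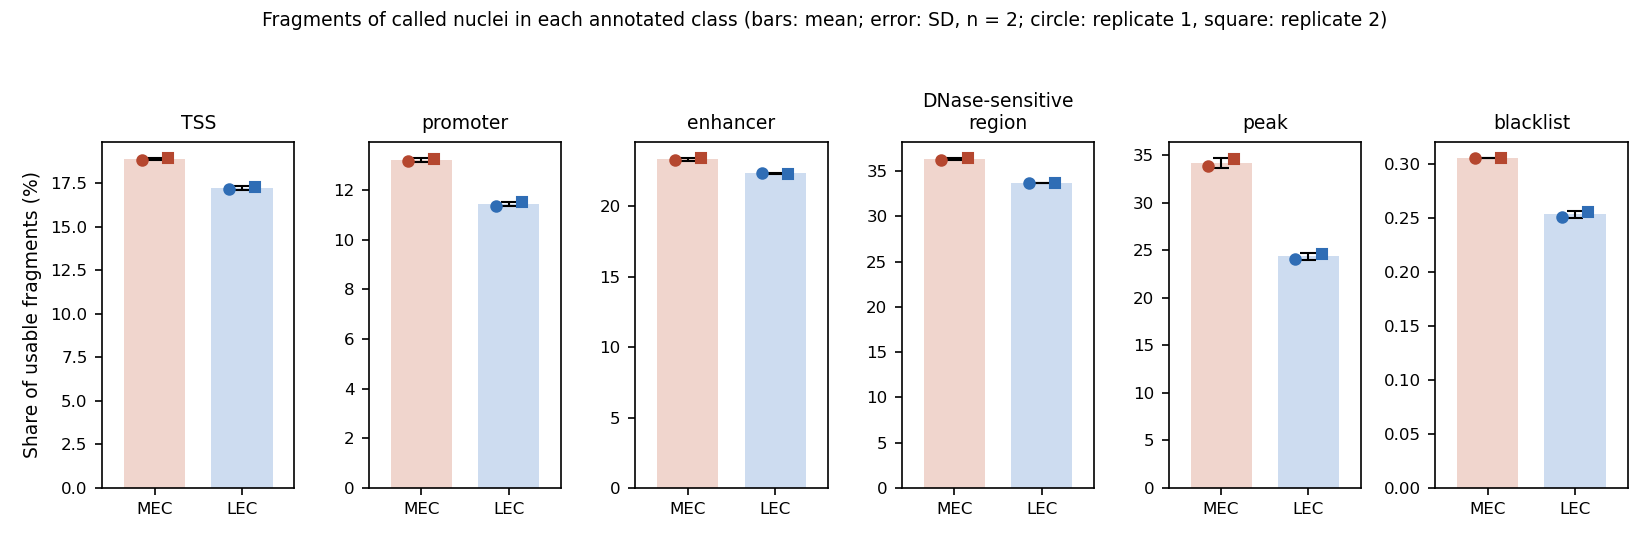
Share of usable fragments of called nuclei (%, vertical axis, from 0) in 6 annotated classes for MEC and LEC. Bars are means, error bars SD over 2 libraries, and points single libraries. Both MEC points lie above both LEC points in each class on this denominator of usable fragments (not over all read pairs for TSSs, enhancers and DNase-sensitive regions), with peaks at 34.2% against 24.4% on average.

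The direction of some of these differences depended on the denominator. Unique fragments at TSSs were 12.2% of all read pairs, duplicates included, in MEC and 12.5% in LEC. The enhancer and DNase-sensitive values were also lower in MEC, while the promoter value stayed higher in MEC at 8.55% against 8.31%. Duplicates enter only the denominator of these values. The higher duplicate share of the MEC libraries therefore lowers their values by construction. In barcodes not called as nuclei, the TSS share was lower than in nuclei of the same library, at 13.2% and 13.6% in the MEC libraries and 12.8% and 12.9% in the LEC libraries. These uncalled barcodes include deep ones and are not a measure of ambient DNA. Barcodes with at least 50 and under 1000 read pairs, which resemble empty droplets, had TSS shares of 17.1% and 18.1% in the MEC libraries and 15.8% and 14.96% in the LEC libraries.

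Enhancer and promoter accessibility did not differ between the regions in proportion. In MEC nuclei there were 1.77 ± 0.00309 enhancer fragments for each promoter fragment, and in LEC nuclei 1.95 ± 0.0163. The ratio was lower in both MEC libraries than in either LEC library (exact permutation p = 0.333), and it stayed lower in MEC under each alternative way of computing it over all nuclei, with differences from -0.336 with nuclei weighted to 1 depth distribution to -0.154 as a mean per nucleus. Within depth classes the difference reached -0.451 between 40000 and 60000 fragments, but below 10000 fragments, where the smallest library held 46 nuclei, the ratio was higher in MEC, at 1.25 ± 0.00995 against 1.19 ± 0.0116.

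The TSS share also went with the depth of a nucleus. In nuclei with 20000 to 40000 usable fragments the TSS share was 26.0% ± 0.536 in MEC and 21.7% ± 0.459 in LEC. In nuclei with 80000 or more fragments it was 16.3% ± 0.0227 and 14.7% ± 0.0832. In these depth classes and those between them both MEC libraries lay above both LEC libraries. Between 10000 and 20000 fragments the libraries of the regions overlapped. Below 10000 fragments, where the smallest library held 46 nuclei, the shares were 25.3% ± 0.254 in MEC and 25.6% ± 0.163 in LEC. With nuclei weighted to 1 depth distribution the TSS share was 19.5% ± 0.258 in MEC and 16.7% ± 0.242 in LEC, a difference of 2.86 percentage points that is 1.74 times the unweighted one. MEC nuclei were sequenced more deeply at nearly equal estimated complexity, so nuclei with equal usable fragments may be less complex ones in MEC. The depth classes, here and for the enhancer to promoter ratio, and this weighting may therefore compare unlike nuclei.

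**Figure D2:**
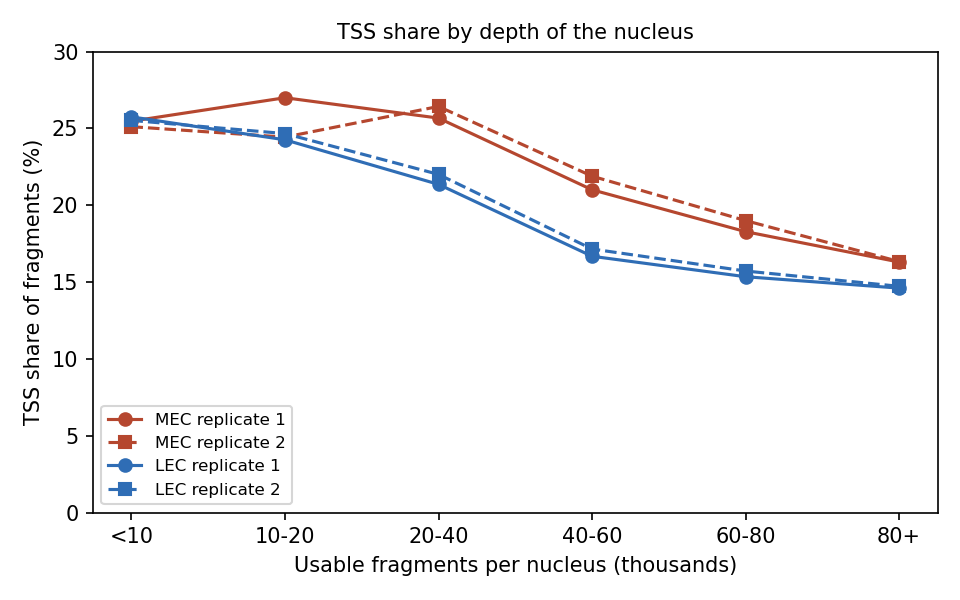
TSS share of fragments (%, vertical axis) against usable fragments per nucleus (horizontal axis, labelled in units of 1000, 6 classes) for each of the 4 libraries. Lines join the pooled shares of 1 library. The share is lower in deeper nuclei of each library from 20000 fragments upward, and MEC lies above LEC from 20000 fragments upward.

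In percentage points, the largest difference among the 6 annotated classes was at peaks. MEC nuclei had 34.2% ± 0.522 of fragments in peaks and LEC nuclei 24.4% ± 0.382, a 1.40-fold difference (exact permutation p = 0.333). The difference of 9.81 percentage points was 4.41 over all read pairs and 4.24 after subtracting the share in uncalled barcodes. It is not stated whether 1 peak set was used for both regions. If peaks were called per library, the peak share also depends on how many peaks a library of that depth allowed, unlike the fixed annotation classes.

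Mitochondrial DNA, a measure of organelle carry-over, made up 1.48% ± 0.114 of read pairs in MEC nuclei and 0.823% ± 0.0434 in LEC nuclei. This pooled value rested on few nuclei. The 5% of nuclei with the highest mitochondrial share held 64.9% and 59.9% of all mitochondrial pairs in the MEC libraries and 25.4% and 24.1% in the LEC libraries. The median nucleus showed the opposite order, with 0.308% ± 0.00818 in MEC and 0.498% ± 0.0248 in LEC (exact permutation p = 0.333). In uncalled barcodes the mitochondrial share was far higher, between 33.9% and 37.1%. Fragments outside called nuclei were 18.8% ± 1.03 of all usable fragments in MEC and 24.3% ± 1.66 in LEC. Most of them were in uncalled barcodes with at least 5000 fragments, which held 13.1% and 12.6% of all fragments in the MEC libraries and 17.3% and 14.2% in the LEC libraries. With every barcode of at least 5000 fragments counted as a nucleus, the share outside nuclei was 6.09% in MEC and 8.76% in LEC, a difference of -2.67 percentage points.

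Nuclei fell into a lower and a higher range of the enhancer to promoter ratio, which was examined after the histograms had been seen. In each of the 4 libraries 2 components described the log2 ratio better than 1, by 65.3 to 183 BIC units, and better than 3. The lower component was centred on a ratio of 1.30 ± 0.00352 in MEC and 1.36 ± 0.0141 in LEC, and the higher on 1.98 ± 0.00842 and 2.19 ± 0.0110. The lower component, fitted per library, held 38.4% ± 0.490 of nuclei in MEC and 36.8% ± 0.402 in LEC. With 1 boundary for all libraries the regions lay further apart, with 40.1% and 39.6% of nuclei below a ratio of 1.6 in the MEC libraries and 30.7% and 32.5% in the LEC libraries. Nuclei of the higher component had 2.50 ± 0.180 times as many fragments as those of the lower one in MEC and 2.71 ± 0.0744 times as many in LEC. TSSs took 26.1% ± 0.00321 of fragments in low-ratio nuclei of MEC and 24.1% ± 0.169 in those of LEC, and 17.0% ± 0.0685 and 15.7% ± 0.0868 in high-ratio nuclei. Enhancers also took less in high-ratio nuclei, at 22.4% against 26.9% in MEC and 21.7% against 25.3% in LEC. DNase-sensitive regions (33.9% against 45.5% and 31.8% against 41.9%) and peaks (32.7% against 39.7% and 23.1% against 29.8%) showed the same order. A higher ratio thus did not go with a larger enhancer share. The split itself uses promoter counts, so a contrast between the components at promoters and TSSs is partly fixed by it. The components are ranges of a score and not cell types, and 23.3% of MEC nuclei and 15.1% of LEC nuclei had a probability under 0.9 for the component they were assigned to.

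**Figure D3:**
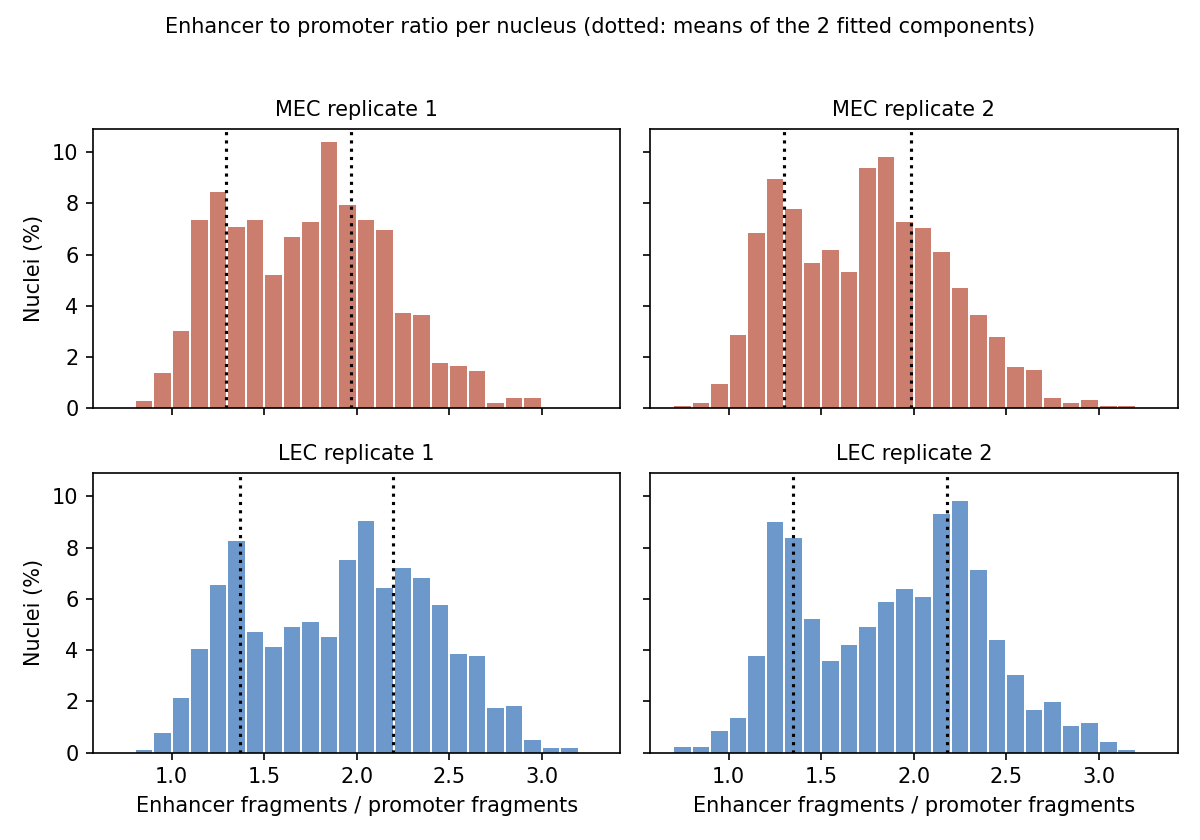
Share of nuclei (%, vertical axis) by enhancer to promoter fragment ratio (horizontal axis) in each of the 4 libraries, for called nuclei with at least 5000 usable fragments. Dotted lines mark the means of the 2 fitted components, near 1.30 and 1.98 in MEC and 1.36 and 2.19 in LEC.

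Whole distributions of nuclei differed more between regions than within them. For the TSS share, the Kolmogorov-Smirnov distance was 0.0220 between the MEC libraries and 0.0457 between the LEC libraries, and between 0.193 and 0.199 across regions. For log10 fragments it was 0.0572 and 0.0686 within regions and 0.178 to 0.270 across. The deeper sequencing of MEC nuclei enters the distances for log10 fragments and, as the TSS share went with depth, can enter the others. Of the 3 ways to divide the libraries into pairs, the division by region gave the highest contrast for both measures, which is the most that 4 libraries can show.

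No excess of barcodes called in more than 1 library was found. Over the 6 pairs of libraries, 8 barcodes were called in both members of a pair, against 23.4 expected among barcodes listed in both tables and 12.001 among barcodes listed in either. Called barcodes were listed in another table more often than control barcodes, as given below, which raises the first expectation. The apparent deficit against it is thus no result. None of the 6 pairs passed 0.05 in the exact hypergeometric test after adjustment (smallest adjusted p = 0.178, for fewer shared barcodes than expected, with 1 pair below 0.05 unadjusted). Among barcodes listed in either, the smallest adjusted p of this test was 0.670. A nucleus barcode of 1 library nevertheless often carried a few reads in another. Between 64.0% and 99.6% of barcodes called in 1 library had at least 1 read pair in another, against 46.6% to 52.7% of control barcodes, and the share was higher in 12 of 12 ordered pairs. The median of usable fragments at such barcodes was between 0 and 20, and 0 at barcodes called in neither library. The mean, which a few barcodes with many fragments dominate, was higher at called barcodes in 3 of the 12 ordered pairs.

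**Figure D4:**
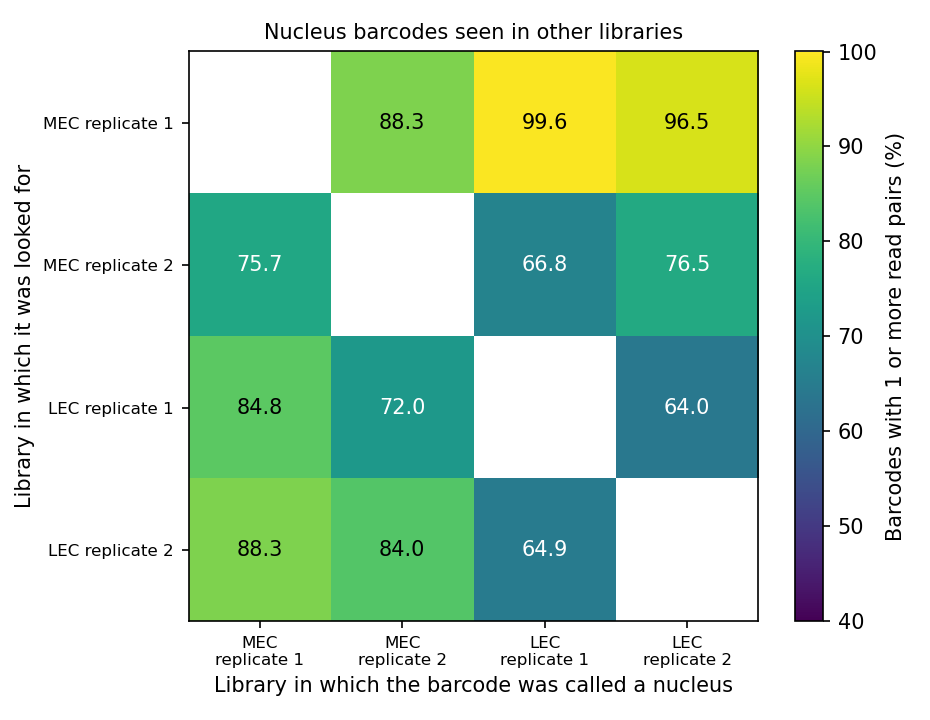
Share of barcodes called as nuclei in 1 library (columns) that had 1 or more read pairs in another (rows), in % (colour scale from 40 to 100). The highest value, 99.6%, is for LEC replicate 1 nuclei in MEC replicate 1, and the lowest, 64.0%, for LEC replicate 2 nuclei in LEC replicate 1.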

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

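Barcodes that the authors had not called as nuclei held a large number of fragments and enter the comparisons above only through the values given for uncalled barcodes, the share outside nuclei and the alternative definitions of a nucleus. Those with at least 5000 usable fragments numbered 149 in MEC replicate 1, 140 in MEC replicate 2, 240 in LEC replicate 1 and 190 in LEC replicate 2. They took 13.1%, 12.6%, 17.3% and 14.2% of all usable fragments of these libraries. The deepest of them, with 291346 fragments in MEC replicate 2, exceeded the deepest called nucleus of its library at 202977, and the same order held in the other libraries (255767 against 154476 in MEC replicate 1, 137693 against 119280 in LEC replicate 1 and 235843 against 158167 in LEC replicate 2). Their median TSS share was 12.8%, 13.2%, 11.9% and 12.5%, against 19.1%, 19.1%, 17.3% and 17.3% in called nuclei. Their enhancer to promoter ratio, 2.98 and 2.99 in the MEC libraries and 3.11 and 3.03 in the LEC libraries, was above the mean of the high-ratio nuclei.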

How the results depend on the processing

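The 12 values compared between regions, the distances, the barcode overlap and the 3 component values were recomputed under 167 alternatives, of which 159 kept the direction of the difference. The component alternatives and the removal of mitochondrial outliers were chosen after seeing the data. With all read pairs as denominator, the MEC minus LEC difference became -0.309 percentage points for the TSS share, -1.13 for enhancers and -0.966 for DNase-sensitive regions, since MEC had more duplicates in that denominator. The mitochondrial difference became -0.190 as a median per nucleus and -0.0529 without the 5% of nuclei with the highest mitochondrial share. The background share difference became 7.77 under the stricter nucleus filter, which counts nuclei above 50000 fragments as background. The difference in called nuclei ranged from -76 to 10 when 1 library was left out, with positive values without MEC replicate 2 and without LEC replicate 1. Leaving out any library turned none of the other values compared between regions. This was certain beforehand, since for each of them both MEC libraries lay on 1 side of both LEC libraries. The distances and the barcode overlap were not recomputed in this way. For nuclei, fixed thresholds of 1000 and 5000 fragments and the stricter filter gave -140.5, -91 and -152. The stricter filter raised the TSS difference to 4.17 and the mitochondrial one to 3.28 (1.12 over usable plus mitochondrial pairs, 1.08 at 1 depth distribution), and lowered that in median fragments to 4360, while complexity left 11.3 fragments. It raised the promoter, enhancer, DNase-sensitive and blacklist differences to 4.45, 2.46, 6.15 and 0.0894, and weighting to 1 depth distribution gave 3.05, 1.55, 4.14 and 0.0752. Over all read pairs the promoter, peak and blacklist differences were 0.239, 4.41 and 0.0136, and after subtracting the share in uncalled barcodes those of TSSs, promoters, DNase-sensitive regions and peaks were 1.09, 1.02, 1.47 and 4.24. Thresholds of 1000 and 5000 fragments brought the background difference to -2.39 and -2.67. In nuclei with 30000 to 60000 fragments the low-ratio share differed by 33.2 percentage points, but the components lay elsewhere there (LEC low at 1.55 and 1.47, MEC high at 1.82 and 1.78), so these are not shares of the same components. With at least 1000 fragments it differed by 0.622. The contrast between the distances across and within regions for log10 fragments fell from 0.165 to 0.106 in nuclei with 3000 to 50000 fragments. For the TSS share it rose from 0.162 to 0.203 there. The replicate block gave the same differences (1.64 percentage points for the TSS share) with an exact sign-flip p of 0.5, the smallest that paired design can give for 2 pairs. By construction it could turn no direction. The log2 ratios of replicate 1 to replicate 2 in MEC and LEC correlated at 0.927 across the 12 values, which are not independent, and no label says what a number marks. The counting intervals of the shares, which leave out variation among nuclei, were far narrower than their differences, and they do not cover the unequal duplicates.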

Other observations

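Apart from the weighting to 1 depth distribution, the share over all read pairs and the duplicate share, which were planned, the tests in this part were chosen after the result they bear on had been seen. The higher TSS share of MEC nuclei was weighed against technical explanations. With nuclei weighted to 1 distribution of usable fragments the difference was 2.86 percentage points, above its replicate SD, so matching on these fragments did not remove it. This match does not settle depth, since MEC nuclei were sequenced more deeply at nearly equal estimated complexity. MEC nuclei with as many usable fragments as LEC nuclei can thus be less complex ones. The TSS share was lower in deeper nuclei, so the match itself may widen the difference. The duplicate share still differed by 8.25 percentage points under that weighting, so sequencing saturation was not matched and stays open. For unique fragments over all read pairs the TSS order was reversed, at -0.309. Duplicates enter only that denominator and lower the MEC value by construction, so this reversal cannot decide the question. How much goes with a different mix of low-ratio and high-ratio nuclei depended on the boundary between them. With both kinds at 1 common weight, 1.45 of the 1.64 percentage points were left with the boundary fitted per library, which moves with the region, and 1.15, 0.975 and 0.816 with boundaries of 1.5, 1.6 and 1.7 for all libraries, where the replicate SD was at most 0.0862. At 1.6, 40.1% and 39.6% of nuclei lay below the boundary in the MEC libraries and 30.7% and 32.5% in the LEC libraries. The split uses promoter counts, which move with the TSS share, so the part left is partly fixed by it. The contribution of the mix is not settled, and mixes of other kinds of nuclei were not tested. Ambient DNA in LEC nuclei would have to supply 20536 fragments per nucleus, or 46.8% of them. The 99th percentile of LEC barcodes with at least 50 and under 1000 read pairs, which resemble empty droplets, was at most 178. These barcodes were chosen for few read pairs, so their percentile was bound to lie far below that number and does not exclude ambient DNA. Wholly separate sequencing runs for the regions are argued against by the reads described in the last paragraph only if these were misassigned after pooling. In the 8 ordered pairs of libraries between regions, called barcodes were seen at least 15.8 percentage points more often than control barcodes. A property of the barcode sequences was not excluded as a source of an excess of that size, so separate runs are not excluded either. Unequal shares of further runs stay open. Library preparation or dissection cannot be told apart from region, because no label gives a preparation. The regions also differed by 7.81 percentage points in duplicates. MEC nuclei were sequenced more deeply at nearly equal estimated complexity, so that difference alone is no sign of unlike preparation. A regional difference in chromatin stays open as well, untested here.

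The 2 ranges of the enhancer to promoter ratio may reflect different kinds of nuclei, such as those of different cell classes, a hypothesis that these tables without genes cannot test. Counting noise is too small, at most 0.0731 of the observed SD of the log2 ratio. Depth of the nuclei stays open. It went with 55.5% to 64.0% of the variance, and after its trend was removed 2 components were preferred over 1 in the MEC libraries, by 22.0 and 49.2 BIC units, but not in the LEC libraries, at -9.40 and -6.84. Among nuclei with 30000 to 60000 fragments 2 components were preferred in each library, by 8.65 BIC units or more, but in only 6 of 20 narrower strata of 10000 fragments. Ambient DNA added to low-ratio nuclei was given the ratio of barcodes resembling empty droplets. By these point values no amount gave the ratio of the high-ratio nuclei in 3 of the 4 libraries. There such barcodes had ratios of 1.89, 1.82 and 2.18 against 1.99, 2.01 and 2.23 in high-ratio nuclei. No uncertainty was computed for these ratios. For LEC replicate 1 (2.18 against 2.23) the gap was smaller than that between such barcodes of the 2 LEC libraries, so it does not decide there. In LEC replicate 2 (2.28 against 2.20) ambient DNA would have to make up 95.9% of the fragments, or 59613 per nucleus. The 99th percentile in such barcodes was at most 179, but they were chosen for few read pairs, so that comparison was fixed in advance. A single skewed distribution was not tested.

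Reads at barcodes called in another library are a candidate sign of reads assigned to the wrong library after pooling. That explanation predicts that such barcodes are seen more often than control barcodes, with a lower mitochondrial share, and with more reads the more pairs they hold in their own library. All 3 predictions held in 12 of 12 ordered pairs, but the first is the observation to be explained and adds no support. The last 2 of these were tested, as a pooled share and as a mean, among barcodes with at most 20 read pairs in the other library, which left out, in MEC replicate 1, 609 of the 1080 barcodes called in LEC replicate 1 alone of the pair. With nuclei in 3 equal classes of own read pairs and no such limit, the median was higher in the top than in the lowest class in 9 of the 12, and equal in all 3 classes in the other 3. The mitochondrial share was 2.01% to 14.4% at such barcodes and 16.1% to 21.7% at control barcodes. A property of the barcode sequences alone would raise a barcode alike in every library. Nuclei of LEC replicate 1 were seen 32.9 percentage points more often in MEC replicate 1 than in MEC replicate 2. Controls varied by 6.11. Their share in MEC replicate 1 was, however, the highest of all ordered pairs. The same nuclei were seen alike in MEC replicate 2 (66.8%, controls 50.9%) and LEC replicate 2 (64.9%, controls 46.6%). A barcode property is therefore not excluded as a part of the excess. The number of reads in the other library was small, a median of 0.0014% to 0.0365% of a nucleus's own read pairs.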
